A study of Homo sapiens with 8 samples.

How the data were processed

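RNA was sequenced from BEAS-2B cells, a transformed line of human bronchial epithelium, after lipofection with 1 of 4 small RNAs: a mimic control, a miR-26 mimic, an inhibitor control or a miR-26 antagomir (an antisense inhibitor). Each transfection was sampled unstimulated and after 6 h with TNF at 50 ng/ml, which gave 8 conditions with 1 library each. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples. The mimic and its control are called the mimic arm here, and the antagomir and its control the antagomir arm.

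The authors aligned reads with TopHat 1.3.3 to hg19, per the labels. The deposited table gave log2 values for 37363 RefSeq transcripts in 8 columns; the base 2 was inferred from the values, since no header names it. The sources used here do not state the quantifier, the annotation release or what the values were divided by. Of the values, 68.4% were exactly 0, and none lay below 0. Over the 8 libraries 5568 values lay between 0 and 0.5 and 8250 between 1.5 and 2. Levels under 1 may have been set to 0, which these values do not settle. A gene "listed at 0" is not shown to be absent. No table of counts was used here, so the depth of each library is unknown and no counting interval or detection limit could be computed. The unit differed from the linear normalized expression assumed when the analysis was designed, and values were returned to the linear scale before the planned steps were applied.

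Levels, as 2 to the power of the value, with exact zeros entered as a level of 0, were summed over the transcripts of each gene symbol, and 268 transcripts with no symbol were left out, 38 of them above 0 in any library. A pseudocount of 1 was added and log2 taken, which leaves a gap of 1 on the log2 scale between a gene listed at 0 and the smallest level above 0. Genes with a mean level of at least 1 over the 8 libraries were tested, 10096 of 22793 symbols. No further normalization was applied. limma 3.58.1 in R 4.3.3 fitted 1 linear model per gene, with a term for each of the 4 transfections and a term for stimulation, leaving 3 residual degrees of freedom, with a mean-variance trend. The residual spread is thus how much the 4 transfections differed in their response to TNF. Contrasts gave the effect of TNF over 4 pairs of libraries, of the mimic over 2 pairs, of the antagomir over 2 pairs, and the difference between the mimic and antagomir effects. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values are given as fitted log2 fold change ± the standard error from limma.

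24 gene lists with 519 entries were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 22 lists that had at least 2 tested members, and again with an estimated correlation. The lists covered miR-26 targets from earlier work, miR-26 host genes, cytokines and chemokines, NF-kB feedback and response genes, TNF to NF-kB signalling components, interferon-stimulated genes and MHC class I antigen presentation. They covered immediate early and AP-1 genes, G1/S and DNA replication genes, G2/M and mitosis genes, the PRC2 complex, the microRNA pathway, p53 targets, unfolded protein and amino acid stress, oxidative stress (NRF2) and cholesterol biosynthesis. The rest were extracellular matrix and TGF-beta response, bronchial epithelial markers, markers of leukocytes, endothelium and fibroblasts, replication-dependent histones, ribosomal proteins and mitochondrially encoded genes. None of the mitochondrially encoded symbols was in the file, and 14 entries in all were not found by symbol.

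The response to TNF was compared between a small RNA and its control as a difference of log2 differences, without a test, since each value rests on 1 library per condition. The genes used were those called as induced at least 2-fold, and the median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. For seed sites, the longest annotated 3-prime UTR of each gene in GENCODE 29 (GRCh38) was searched for the 8mer TACTTGAA, the 7mer-m8 TACTTGA and the 7mer-A1 ACTTGAA. Genes holding none of these and no 6mer ACTTGA were the background. UTRs of at least 50 nt were found for 9472 tested genes (93.8%). Coordinates are on GRCh38, not on the build the authors aligned to, and no value was placed by coordinate.

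The 4 named targets, the lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took HMGA1, MALT1, IL6 and EZH2, then the 10 largest called changes in each direction that went the same way in every pair of libraries. These were filled where fewer were called with the smallest p among genes above the 25th percentile of mean expression. It also took up to 4 members with the smallest p from each list with at least 5 measured members, of which some are printed, and the 5 largest double differences in each direction. Not every gene the rule took is printed. Alternatives fixed in the same way were quantile normalization, no filter, a pseudocount of 0.1, limma without the trend, each arm alone, no transfection or stimulation term, each library left out, a stricter fold or mean level, and other site classes and backgrounds. Alternatives added after the data were seen were genes above 0 in all 8 libraries, levels under 1 set to 1, and removal of a trend with UTR length and base composition. The left-out libraries for the lists and for the difference of effects, limma without the trend for that difference, the comparisons between arms, and the ranking of all 7mers with that trend removed, were also added after the data were seen.

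The fit was tested on simulated data with 200 changed genes in each of 5 simulations. At a 2-fold change 59% were recovered for TNF, 28.2% for the mimic and 29.6% for the antagomir, and at 4-fold 82%, 65.6% and 66.4%. For the difference between the mimic and antagomir effects, 3.4% and 39.4% were recovered. A list shifted by 0.5 was called by camera in 20 of 20 simulations, with 1 of 420 other lists. In all these simulations genes varied independently, none was set to 0, and no spread between transfections was added. The rates for the mimic, the antagomir and their difference therefore leave out that spread. Nor do the rates show how camera performs on lists of correlated genes. Sequence searches and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.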

Results

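The data were 8 RNA-seq libraries of BEAS-2B human bronchial epithelial cells, 1 for each combination of 4 transfections with stimulation by TNF or none, so no condition was replicated. The libraries listed 11547 to 12101 transcripts above 0, and their linear levels summed to between 303448 and 365015. Read depth is unknown. Across tested genes, which are not independent replicates, Pearson r between libraries was 0.88 to 0.91 with the same stimulation and 0.84 to 0.88 with different stimulation. The first principal component (31.0% of variance) separated TNF from unstimulated libraries, and the next (16.8%) separated the mimic arm from the antagomir arm.

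HMGA1, an architectural chromatin protein, MALT1, a paracaspase and scaffold of NF-kB signalling, and IL6, a proinflammatory cytokine, are the genes the study's title names. On GRCh38 with GENCODE 29, HMGA1 lies on chromosome 6 (34236873 to 34246231), MALT1 on chromosome 18 (58671386 to 58754477) and IL6 on chromosome 7 (22725884 to 22732002). The 3-prime UTR of HMGA1 held a miR-26 8mer at 34246201 to 34246208, that of MALT1 an 8mer at 58749945 to 58749952, and that of IL6 a 7mer-A1 at 22731783 to 22731789. EZH2, the methyltransferase of PRC2 and a miR-26 target from earlier work, lies on chromosome 7 (148807383 to 148884321) with an 8mer at 148807389 to 148807396. Unstimulated HMGA1 was 6.12 on the log2 scale with the mimic control, 4.53 with the mimic, 4.54 with the inhibitor control and 5.04 with the antagomir, and with TNF it was 7.44, 5.90, 7.10 and 7.01. Unstimulated MALT1 was 3.0, 1.55, 2.76 and 1.03 in the same order, and with TNF 3.30, 1.66, 3.05 and 1.22. IL6 was listed at 0 in the unstimulated mimic control and was 1.15, 2.60 and 2.02 in the other unstimulated libraries, and with TNF it was 3.38, 3.25, 5.31 and 4.93. Unstimulated EZH2 was 4.05, 4.39, 4.67 and 4.68, and with TNF 4.09, 4.28, 4.29 and 3.84.

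**Figure D1:**
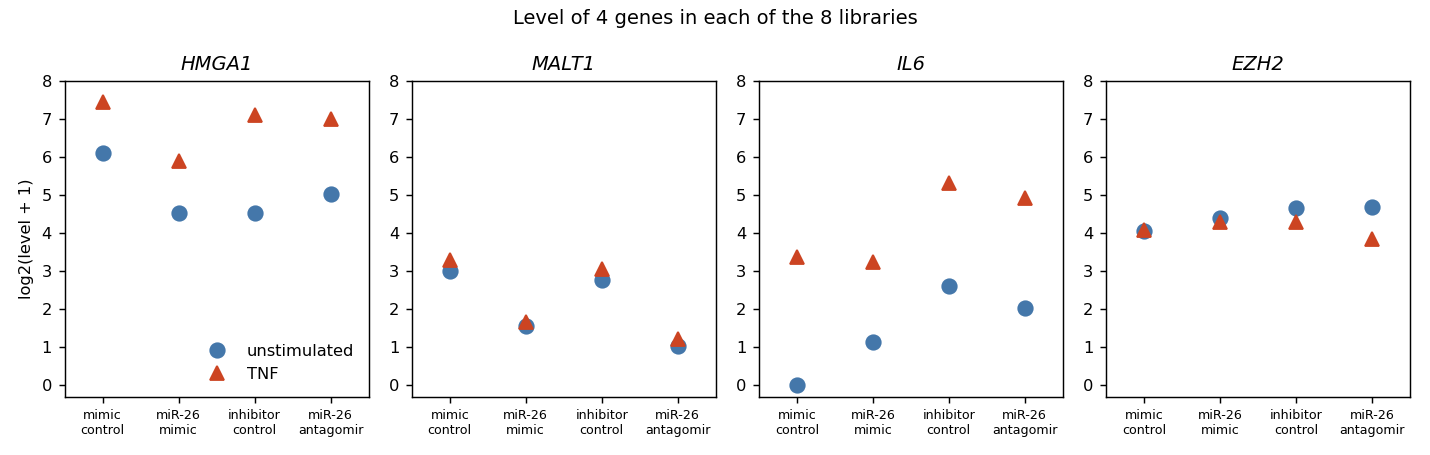
Level of HMGA1, MALT1, IL6 and EZH2 in each of the 8 libraries, as log2 of the level plus 1, by transfection (x axis), unstimulated (circles) and with TNF (triangles), 1 library per point. MALT1 lay between 1.03 and 1.66 in the 4 libraries with the mimic or the antagomir and between 2.76 and 3.30 in the 4 control libraries. On this scale every level above 0 lies above 1, so the lowest MALT1 values lie near that floor.

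The comparison of TNF with unstimulated libraries asked which genes respond to the cytokine in these cells. CXCL8, a chemokine that attracts neutrophils, rose by 7.40 ± 0.13 (limma adjusted p = 0.0004329) and CXCL1, of the same kind, by 5.65 ± 0.13 (adjusted p = 0.0005058), each higher in 4 of 4 pairs. Both were listed at 0 in the 2 unstimulated libraries of the mimic arm. CCL2, which attracts monocytes, rose by 6.05 ± 0.13 (adjusted p = 0.0005058; higher in 4 of 4 pairs). IL32, another proinflammatory cytokine, rose by 5.54 ± 0.38. TNIP1, an inhibitor of NF-kB signalling, rose by 5.96 ± 0.56, and SOD2, the mitochondrial superoxide dismutase, by 5.50 ± 0.97, each listed at 0 in 1 unstimulated library. TNFAIP3, the ubiquitin-editing brake on NF-kB, was listed at 0 in all 4 unstimulated libraries and reached 5.30, 5.36, 5.74 and 5.41 with TNF. PTX3, a soluble pattern recognition protein, went from 0 in all 4 to 5.72, 5.30, 5.97 and 6.17. CSF2, a myeloid growth factor, went likewise to 5.06, 5.29, 5.81 and 5.70, and the transcription factor gene CREB3 to 5.86, 5.82, 5.75 and 6.03. IL6 rose by 2.78 ± 0.23 (adjusted p = 0.007941) and HMGA1 by 1.81 ± 0.24 (adjusted p = 0.01957). MALT1 at 0.22 ± 0.11 (adjusted p = 0.2387) and EZH2 at -0.32 ± 0.16 (adjusted p = 0.2535) were not called.

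Among the genes that fell with TNF, KANK2, an adhesion and actin regulator, fell by 2.61 ± 0.37 on the log2 scale. BMP4, a growth factor of the TGF-beta family, fell by 2.20 ± 0.16, and RIMS4 fell by 2.13 ± 0.31, listed at 0 in both TNF libraries of the antagomir arm. SNAI1, a repressor of epithelial genes, fell by 2.15 ± 0.17 and was listed at 0 in the mimic control with TNF. AHRR, the repressor of the aryl hydrocarbon receptor, was 2.20, 1.88, 2.77 and 2.87 in the unstimulated libraries and was listed at 0 in all 4 with TNF. The kinase gene TNK1 went from 2.44, 2.07, 2.45 and 2.45 to 0 in all 4. So did MEDAG from 2.09, 2.42, 2.26 and 2.16, the transcription factor gene HLF from 2.29, 1.84, 2.44 and 2.14, and RBM26 from 2.67, 1.91, 2.21 and 1.76. In all, 1258 of 10096 genes were called, 538 higher and 720 lower. Of these, 258 rose and 114 fell at least 2-fold, and 71 had all libraries of one side at 0. An unadjusted p under 0.05 was found for 3203 genes against 505 by chance. The median over all tested genes was -0.11, and quantile normalization moved it to -0.06 with 47.3% of calls higher in place of 42.8%. No gene was called in either arm fitted alone, with 1932 and 1779 genes at an unadjusted p under 0.05 in limma. An arm alone leaves fewer residual degrees of freedom than the full fit, here and in the comparisons below. Leaving out any 1 library gave between 95 and 306 genes.

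NF-kB feedback and response genes rose together: 34 of 40 measured members were called higher and none lower (39 adjusted over the list alone), with a median of 2.43. NFKBIA, the inhibitor that retains NF-kB in the cytoplasm, rose by 3.48 ± 0.08 and ICAM1, a leukocyte adhesion molecule, by 5.22 ± 0.16. The camera adjusted p was 1.01e-36 with the preset correlation, and adjusted p = 0.0931 with an estimated correlation. Of 21 measured cytokines and chemokines 16 rose and none fell (18 adjusted over the list alone), with a median of 2.95 (camera adjusted p = 4.789e-20; adjusted p = 0.0931 with an estimated correlation). Among TNF to NF-kB signalling components, RELA, the activating NF-kB subunit, rose by 0.66 ± 0.05, TRAF2, an adaptor of the TNF receptor, by 0.72 ± 0.11, and the receptor gene TNFRSF1A fell by 0.40 ± 0.07. Of 25 measured, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.03741; adjusted p = 0.406 with an estimated correlation). The list median was -0.02 with the mimic control, 0.10 with the mimic, 0.13 with the inhibitor control and 0.08 with the antagomir.

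Of 35 measured interferon-stimulated genes 17 rose and none fell (27 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 3.205e-17; adjusted p = 0.406 with an estimated correlation). GBP1, an interferon-induced GTPase, rose by 1.62 ± 0.13 and IFIT3, an antiviral protein, by 2.69 ± 0.24. DDX58, the RNA sensor RIG-I, rose by 2.48 ± 0.23 and OAS3, which synthesizes 2'-5' oligoadenylates, by 2.23 ± 0.23. The median response of the list was 1.05 with the mimic control, 1.19 with the mimic, 2.59 with the inhibitor control and 2.61 with the antagomir. Of 7 measured genes of MHC class I antigen presentation 5 rose and none fell (6 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 1.912e-06; adjusted p = 0.281 with an estimated correlation). Of these PSMB10, an immunoproteasome subunit, rose by 1.80 ± 0.18, the peptide-trimming peptidases ERAP1 by 1.15 ± 0.10 and ERAP2 by 0.74 ± 0.07, and B2M, the light chain of MHC class I, by 0.53 ± 0.09. The list holds 17 genes, all in the file, and only 7 reached the mean level for testing, so most of it is not covered.

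G2/M and mitosis genes fell together. Of 29 measured members 16 fell and none rose (21 lower and 1 higher adjusted over the list alone), with a median of -0.40 (camera adjusted p = 9.428e-07; adjusted p = 0.281 with an estimated correlation). KIF20A, a mitotic kinesin, fell by 0.72 ± 0.06, NUSAP1, a spindle protein, by 0.66 ± 0.05, HMMR by 0.55 ± 0.05 and cyclin gene CCNB2 by 0.52 ± 0.05. Of 32 measured G1/S and DNA replication genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; median -0.29, camera adjusted p = 0.05947). CCND1, cyclin D1, rose by 1.17 ± 0.18 and its partner kinase CDK6 by 0.73 ± 0.09. The replicative helicase subunits MCM2 and MCM3 fell by 0.47 ± 0.07 and 0.33 ± 0.06. Of 11 measured bronchial epithelial markers 4 rose and none fell (5 higher and 1 lower adjusted over the list alone; median 0.12, camera adjusted p = 0.01208; adjusted p = 0.406 with an estimated correlation). The list median was 0.36 with the mimic control, 0.26 with the mimic and 0.26 with the antagomir, but -0.15 with the inhibitor control. CLDN1, a tight junction protein, rose by 3.89 ± 0.09, LAMB3, a laminin chain of the basement membrane, by 2.74 ± 0.11, and the keratin KRT17 by 0.44 ± 0.08. The call of this list was lost with quantile normalization (adjusted p = 0.127) and with the UTR trend removed (adjusted p = 0.104). Of 27 measured extracellular matrix and TGF-beta response genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.18, camera adjusted p = 0.0291; adjusted p = 0.281 with an estimated correlation). The list median was 0.03, 0.24, 0.07 and -0.03 with the mimic control, mimic, inhibitor control and antagomir. TGFB2, a growth factor, rose by 1.82 ± 0.26, and the collagens COL4A1 by 0.96 ± 0.13 and COL6A1 by 0.68 ± 0.11. With quantile normalization the call of this list was lost (adjusted p = 0.205).

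**Figure D2:**
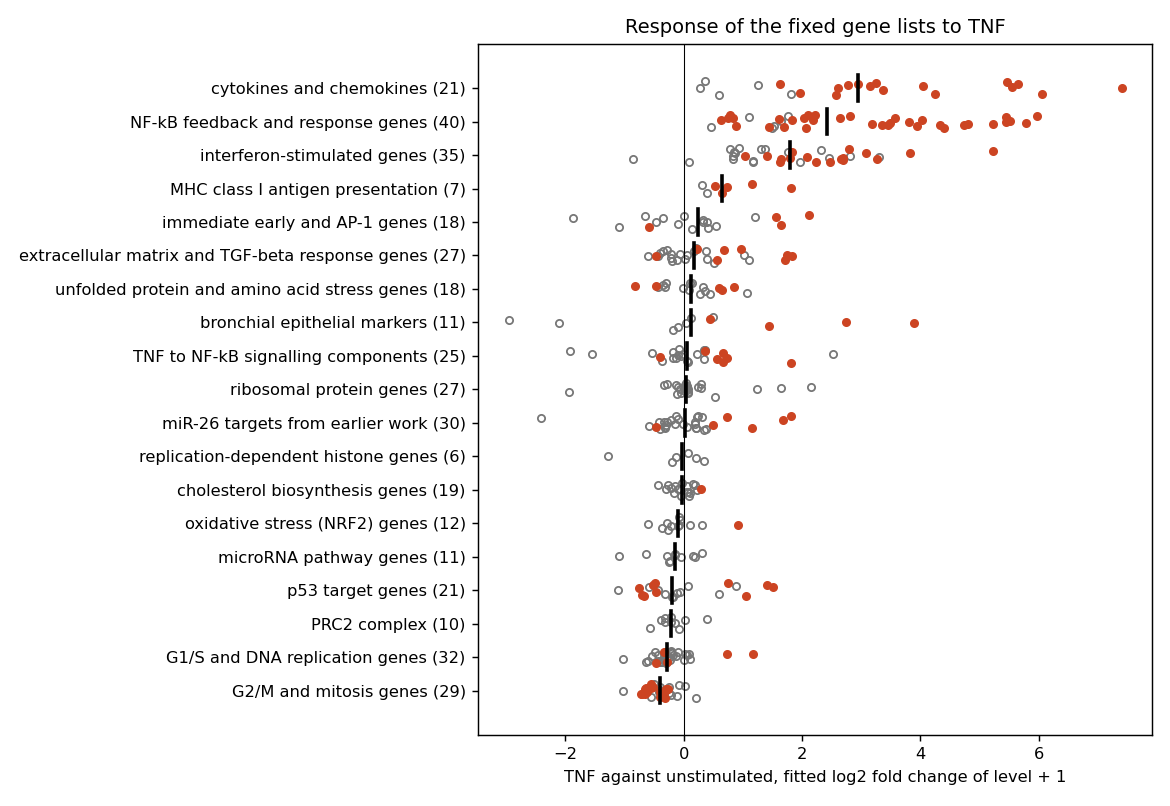
Fitted log2 fold change with TNF (x axis) of each measured member of the fixed lists with at least 5 members, filled where limma called the gene and open where it did not. Bars mark the median of each list and brackets hold the number of members. Medians ran from -0.40 for G2/M and mitosis genes to 2.95 for cytokines and chemokines.

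Camera did not call 14 lists for TNF, the G1/S list among them (adjusted p 0.058 to 0.948, medians -0.48 to 0.23). Of 18 measured immediate early and AP-1 genes 3 rose and 1 fell (5 and 2 adjusted over the list alone). The AP-1 subunit FOSL1 rose by 2.11 ± 0.12, MAFF by 1.55 ± 0.09 and the ERK phosphatase DUSP6, listed at 0 in the unstimulated libraries of the mimic arm, by 1.65 ± 0.21, and EGR1 fell by 0.58 ± 0.07. Of 21 measured p53 targets 4 rose and 6 fell (5 and 7 adjusted over the list alone). Among them were the death receptor TNFRSF10B at 1.5 ± 0.08, PLK3 at 1.41 ± 0.19, AEN at 0.75 ± 0.09 and the DNA repair gene DDB2 at -0.68 ± 0.08. Of 18 unfolded protein and amino acid stress genes 3 rose and 2 fell (5 and 5 adjusted over the list alone). HERPUD1 was at 0.85 ± 0.05, XBP1 at 0.60 ± 0.10, the amino acid transporter SLC7A5 at -0.83 ± 0.09 and PHGDH, of serine synthesis, at -0.48 ± 0.07. Of 30 miR-26 targets from earlier work 5 rose and 1 fell (6 and 7 adjusted over the list alone). Among them were the apoptosis gene BID at 1.68 ± 0.09 and the Notch ligand JAG1 at 1.15 ± 0.18. FTH1, the ferritin heavy chain, rose by 0.92 ± 0.11 as 1 of 12 NRF2 genes, and SQLE, of sterol synthesis, by 0.29 ± 0.06 as 1 of 19 cholesterol genes. No member was called among 10 PRC2, 11 microRNA pathway, 3 miR-26 host, 6 histone and 27 ribosomal protein genes in limma. Adjusted over the list alone, 2 host genes and 1 histone gene were lower, and none in the other lists of these. The median of the host genes was -0.40 with the mimic control, -0.44 with the mimic, -0.78 with the inhibitor control and -0.81 with the antagomir. Of the markers of other cell types, 9 endothelial genes were listed at 0 in every library, none of 2 measured leukocyte genes was called and 1 of 4 fibroblast genes fell.

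The comparison of the miR-26 mimic with its control asked which genes a raised level of the microRNA changes. SUMO2, a ubiquitin-like modifier, fell by 1.32 ± 0.07 on the log2 scale and RGS4, a regulator of G-protein signalling, by 1.45 ± 0.08 (limma adjusted p = 0.03607 for each; lower in 2 of 2 pairs). RGS4 held a miR-26 8mer on chromosome 1 at 163076026 to 163076033, and SUMO2 held no site. NPPB, which encodes a natriuretic peptide, rose by 1.41 ± 0.09 and PACS1, a sorting protein of the trans-Golgi network, by 2.24 ± 0.15 (adjusted p = 0.03688 for each). PACS1 was 1.93 and 1.87 with the mimic control, 4.12 and 4.15 with the mimic, and between 3.92 and 4.47 in the antagomir arm. HMGA1 at -1.56 ± 0.34 (adjusted p = 0.2138) and MALT1 at -1.54 ± 0.15 (adjusted p = 0.0824) were not called. Part of the HMGA1 difference lies in a transcript at 3.88 and 4.41 with the mimic control and listed at 0 in every other library. Another HMGA1 transcript was 4.73 and 5.81 with the control and 2.97 and 4.58 with the mimic. A further one was 4.76 and 6.28 against 3.84 and 4.69. In the inhibitor control these 2 transcripts were 3.12 and 3.77 unstimulated and 5.97 and 6.19 with TNF. Both unstimulated mimic values thus lay near those of the inhibitor control, and both with TNF lay below those of either control. Summed over transcripts, unstimulated HMGA1 differed from the mimic control by -1.58 with the mimic and -1.57 with the inhibitor control. With TNF these were -1.54 and -0.34. Without the trend in limma MALT1 passed at adjusted p = 0.035. IL6 at 0.51 ± 0.32 (adjusted p = 0.5186) and EZH2 at 0.27 ± 0.23 (adjusted p = 0.6411) were not called.

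The other 12 called genes were at 0 on one side. CBX3, a heterochromatin protein, was listed at 0 with the mimic control, at 6.23 and 6.13 with the mimic, and between 6.08 and 6.25 in the antagomir arm. PAM, of peptide amidation, was 5.27 and 5.30 with the mimic and the kinetochore gene CENPT 4.05 and 4.41, both at 0 with the control and above 0 in the antagomir arm. The small nucleolar RNAs SNORA21 (4.39 and 5.02) and SNORA69 (4.24 and 3.92), HSP90AA6P (4.38 and 4.40) and DNASE1L1 (3.87 and 3.91) were above 0 with the mimic and at 0 in the other 6 libraries. EEF1E1, of the tRNA synthetase complex, was 5.35 and 5.41 with the control and listed at 0 with the mimic. So listed were PYCR1, of proline synthesis, with 5.02 and 5.14 in the control, PIGF 3.27 and 3.32, CCDC77 3.01 and 2.62, and the Mediator kinase CDK8 2.57 and 2.87. In all, limma called 16 genes, 9 higher and 7 lower, and 1458 had an unadjusted p under 0.05 against 505 by chance. Refitted on the 8279 tested genes above 0 in all 8 libraries alone, limma called none (1404 at an unadjusted p under 0.05; smallest adjusted p 0.0546). None was called in the mimic arm fitted alone (1590), and leaving out any 1 library gave 2 to 10. A comparison of the 2 control transfections, added after the data were seen, called 12 genes in limma. It had 1418 genes at an unadjusted p under 0.05. The fit holds no spread between repeated transfections, so the counts for the mimic are not shown to be its effect. Among genes not called, CNN1, a smooth muscle calponin, was 1.34 ± 0.11 and MSMO1, of sterol synthesis, -1.01 ± 0.08 (adjusted p = 0.05071 for each). LENG8 was -1.53 ± 0.13 (adjusted p = 0.05644) and KPNA2, a nuclear import receptor with a miR-26 8mer, was -0.69 ± 0.06 (adjusted p = 0.067).

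Cholesterol biosynthesis genes were lower as a group with the mimic, with a median of -0.31 over 19 measured members (camera adjusted p = 7.972e-05; adjusted p = 0.430 with an estimated correlation). None was called over all genes tested and 8 were lower adjusted over the list alone, among them DHCR7 at -0.62 ± 0.09, FDFT1 at -0.64 ± 0.10 and HMGCS1 at -0.61 ± 0.11. The list was also lower in the inhibitor control than in the mimic control, in a comparison added after the data were seen (median -0.22, camera adjusted p = 0.0001937; adjusted p = 0.5595 with an estimated correlation). HMGCS1 was 4.83 and 5.20 with the mimic and 4.93 in both inhibitor control libraries. Extracellular matrix and TGF-beta response genes were higher, with a median of 0.33 over 27 members (camera adjusted p = 0.0005889; adjusted p = 0.430 with an estimated correlation), none called and 2 higher and 1 lower adjusted over the list alone. COL1A2, a chain of type I collagen, was 0.71 ± 0.14, TGFBI, an adhesion protein of the matrix, 0.40 ± 0.08, THBS1 0.68 ± 0.15, and TGFB1 -0.45 ± 0.06. Unfolded protein and amino acid stress genes had a median of 0.20 over 18 members (camera adjusted p = 0.002008; adjusted p = 0.430 with an estimated correlation), none called and 1 higher adjusted over the list alone. DDIT4 was at 0.76 ± 0.09, PHGDH at 0.44 ± 0.09 and the chaperone HSP90B1 at 0.32 ± 0.09. The 30 miR-26 targets had a median of -0.12 (camera adjusted p = 0.2008), none called and 1 higher and 4 lower adjusted over the list alone. The receptor kinase EPHA2 was at -0.77 ± 0.14. Camera did not call 19 lists in all (adjusted p 0.0508 to 0.821, medians -0.40 to 0.18), and no member of any was called in limma. The lowest adjusted p of these was that of the bronchial epithelial markers (camera 0.05082, and 0.7818 with an estimated correlation). Their median was -0.33, with -0.39 unstimulated and -0.41 with TNF, and 2 of 11 were higher. Members with small p in the uncalled lists included the keratins KRT7 at -0.84 ± 0.12 and KRT19 at -1.19 ± 0.20. Others were MCM6 at 1.48 ± 0.18, the thymidylate synthase TYMS at 0.66 ± 0.08 and the syndecan SDC4 at 0.88 ± 0.13. CXCL8, at -0.33 ± 0.18 (adjusted p = 0.4829), was listed at 0 in both unstimulated libraries of this arm.

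The comparison of the miR-26 antagomir with its control asked which genes change when the microRNA is inhibited. CCDC127 rose by 2.32 ± 0.11 (limma adjusted p = 0.01541; higher in 2 of 2 pairs), with 2.04 and 2.06 in the inhibitor control and between 4.04 and 4.58 in the other 6 libraries. ANXA2P1, an annexin pseudogene, was 4.62 and 4.97 with the antagomir and listed at 0 elsewhere, and PIGF, of GPI anchor synthesis, was 3.40 and 3.02 with the antagomir and at 0 with the inhibitor control. RPS3A, a ribosomal protein, was 6.51 and 6.21 with the inhibitor control and listed at 0 with the antagomir. So listed were EIF4A1, the translation initiation helicase, with 5.21 and 5.50 in the control, TAF1D 4.27 and 3.99, TREX1, a DNA exonuclease, 3.71 and 3.82, and the corepressor scaffold SIN3A 3.68 and 3.69. Also so listed were the histone chaperone NAP1L4 with 3.82 and 3.51, TMEM110 3.04 and 3.11, and PYCR1 2.59 and 2.61. These 11 genes, 3 higher and 8 lower, were all that limma called, with 648 at an unadjusted p under 0.05 against 505 by chance. Both counts lay below the 12 and 1418 found between the 2 control transfections. MALT1 was -1.78 ± 0.15 (adjusted p = 0.09824; adjusted p = 0.0267 without the trend in limma) and was not called. HMGA1 was 0.21 ± 0.34 (adjusted p = 0.8703), IL6 -0.48 ± 0.32 (adjusted p = 0.6824) and EZH2 -0.22 ± 0.23 (adjusted p = 0.7785), not called. EGR1, an immediate early transcription factor, was -1.30 ± 0.10 (adjusted p = 0.05928) and CTDSPL2 -1.27 ± 0.12 (adjusted p = 0.1389). MRPS28, of the mitochondrial ribosome, was 1.33 ± 0.13, the peroxiredoxin PRDX4 1.09 ± 0.13 and the corepressor CTBP1 0.83 ± 0.09. CACYBP was 0.70 ± 0.09, KIAA0226 0.97 ± 0.13, RIOK2 0.89 ± 0.13 and PTTG1IP 0.45 ± 0.07, with adjusted p between 0.1389 and 0.3933. No gene was called in the antagomir arm fitted alone (387 at an unadjusted p under 0.05 in limma), 1 was in a refit on the 8279 genes above 0 in all 8 libraries, and leaving out any 1 library gave 0 to 27.

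Camera called 7 lists for the antagomir, with no member called over all genes tested in any of them. Ribosomal protein genes were higher (median 0.28, adjusted p = 0.001835; adjusted p = 0.780 with an estimated correlation), with RPL27 at 0.32 ± 0.12 and RPL19 at 0.33 ± 0.14. The list median was 0.03 unstimulated and 0.50 with TNF. In the antagomir library with TNF, deviation from the mean had rho of -0.32 with UTR length across genes, which are not independent replicates. The call was lost with quantile normalization (adjusted p = 0.344) and with the UTR trend removed (adjusted p = 0.575). Immediate early and AP-1 genes were lower (median -0.32, unstimulated -0.44 and with TNF -0.22; adjusted p = 0.001835; adjusted p = 0.646 with an estimated correlation), with DUSP5 at -0.62 ± 0.15, ATF3 at -0.65 ± 0.22 and IER2 at -0.66 ± 0.22, and 1 member adjusted over the list alone. Bronchial epithelial markers were higher (median 0.30, 0.14 and 0.45 in the same order; adjusted p = 0.007068; adjusted p = 0.646 with an estimated correlation), with KRT17 at 0.51 ± 0.11, KRT7 at 0.41 ± 0.12 and the checkpoint protein SFN at 0.34 ± 0.12. Histone genes were higher (median 0.52, 0.46 and 0.37; adjusted p = 0.01893; adjusted p = 0.646 with an estimated correlation), with HIST1H2BD at 0.68 ± 0.20 and HIST1H2BK at 0.31 ± 0.09. Cholesterol biosynthesis genes were higher (median 0.10, 0.15 and 0.01; adjusted p = 0.01893; adjusted p = 0.646 with an estimated correlation), with HMGCS1 at 0.40 ± 0.11 and FDPS at 0.28 ± 0.11. The inhibitor control lay below the mimic control in cholesterol genes, as said, and in epithelial markers (median -0.39, adjusted p = 0.006682, and 0.606 with an estimated correlation). It lay above the mimic control in immediate early and AP-1 genes (median 1.40, camera adjusted p = 9.391e-10, and 0.5595 with an estimated correlation). TNF to NF-kB signalling components were lower (median -0.06, -0.12 and -0.0047; adjusted p = 0.02083; adjusted p = 0.646 with an estimated correlation), with CUL1, a ubiquitin ligase scaffold, at -0.60 ± 0.09. The miR-26 targets from earlier work were lower over the fit (median -0.13, adjusted p = 0.02083; adjusted p = 0.646 with an estimated correlation), but in 1 of 2 pairs alone (0.01 unstimulated and -0.28 with TNF). The signalling and target lists each had 2 members lower adjusted over the list alone. With the UTR trend removed, camera no longer called the miR-26 targets (adjusted p = 0.176), epithelial markers (0.0719) and histones (0.130), and with quantile normalization it no longer called cholesterol genes (0.0858). Camera did not call the other 15 lists (adjusted p 0.257 to 0.983, medians -0.38 to 0.10), in which NFKB1, the p105 subunit of NF-kB, was -0.38 ± 0.13 and CXCL8 -0.41 ± 0.18.

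A repressor and its inhibitor would move direct targets in opposite directions, and the mimic effect was therefore compared with the antagomir effect. Limma called 13 genes as differing, 8 of them higher and 5 lower in the mimic effect, with 1538 at an unadjusted p under 0.05. Those above 0 in all 8 libraries were CCDC127 (difference -2.68 ± 0.16, adjusted p = 0.0235) and SUMO2 (-1.43 ± 0.10, adjusted p = 0.04348). PIGF and CCNL2, a cyclin of splicing, were listed at 0 with the mimic and with the inhibitor control, and TBC1D1, a regulator of glucose transporter traffic, with the mimic control and with the antagomir. CBX3, EEF1E1, EIF4A1, NAP1L4, RPS3A, SIN3A, TREX1 and TMEM110 were at 0 in 1 of the transfections. Refitted on the 8279 tested genes above 0 in all 8 libraries alone, limma called none (1486 at an unadjusted p under 0.05). Across genes, which are not independent replicates, the effects of the mimic and the antagomir had Pearson r of -0.07 and Spearman rho of -0.16. Over the 8279 genes above 0 in all 8 libraries these were -0.14 and -0.21. The effects leaned on UTR length in opposite directions, with rho of 0.17 and 0.15 in the mimic pairs and -0.10 and -0.35 in the antagomir pairs. That trend was not removed from these correlations, so their negative sign is not shown to come from direct targets.

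Whether the mimic or the antagomir changes the response to TNF was examined with the 258 genes induced at least 2-fold. Their response was lower with the mimic than with its control in 174, with a median difference of -0.13, against 0.00 to 0.08 for the central 95% of 10000 random lists, none of which lay lower. TGFB2 had a difference of -1.49, and OLR1, a receptor for oxidized LDL, of -1.67. The cytokine LIF was 0 unstimulated and 5.10 with TNF in the control and 2.81 and 5.66 with the mimic. The protease MMP3 was 0 and 5.05 against 0 and 3.29, and TMEM171 0 and 2.73 against 0 and 1.12. In the other direction the guidance receptor NRP2 had 1.60 and the transcription factor IRF1 1.39. NFKB2 was 2.69 and 5.66 in the control against 0 and 5.80, TNIP1 3.02 and 8.46 against 0 and 7.99, and the RNA sensor IFIH1 1.15 and 2.16 against 0 and 2.90. The 21 cytokines and chemokines had a median difference of -0.22, with 0.69% of random lists lower, and the 40 NF-kB feedback and response genes -0.03, with 6.69% lower. HMGA1 had a difference of 0.05 and IL6 one of -1.27, the latter against a control listed at 0 unstimulated. With 1 library per condition none of these differences was tested.

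With the antagomir the median difference over the 258 induced genes was 0.00, with 129 lower and 20.9% of random lists below. It was 0.17 over cytokines and chemokines, with 93.1% of random lists below, and 0.01 over NF-kB feedback and response genes, with 44.6% below. PDLIM4, an actin-associated protein, had -1.24, the protease inhibitor SERPINB8 1.12 and IRF1 1.00. SOD2 was listed at 0 and 9.10 in the inhibitor control against 3.94 and 8.69 with the antagomir. The NF-kB subunit RELB was 0 and 5.78 against 1.99 and 6.29, APOL3 0 and 4.96 against 1.42 and 4.81, and IFIH1 0 and 4.40 against 1.01 and 3.87. STAT5A was 1.75 and 3.87 against 0 and 3.81, SERPINB2, an inhibitor of urokinase, 1.13 and 4.67 against 0 and 5.0, and MLKL, the effector of necroptosis, 1.14 and 2.26 against 0 and 2.18. HMGA1 had a difference of -0.58 and IL6 of 0.21.

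**Figure D3:**
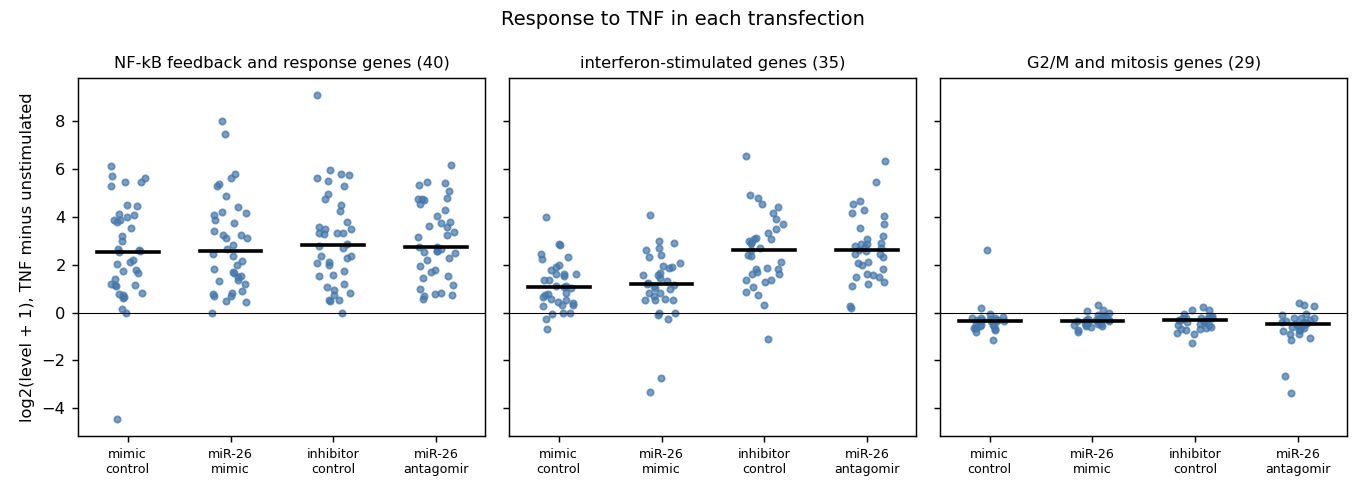
Difference between TNF and unstimulated log2 levels (y axis) of each measured gene of 3 lists in each of the 4 transfections (x axis), with the median as a bar, 1 pair of libraries per column. The median of the interferon-stimulated genes was 1.05 and 1.19 in the mimic arm and 2.59 and 2.61 in the antagomir arm.

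Genes with a miR-26 seed site in the 3-prime UTR were compared with genes without one, since the seed is the part of a microRNA that pairs with its targets. With the mimic the 2281 site genes lay above the 5878 genes without a site, by 0.05 unstimulated (99.2% of matched random lists lower) and 0.03 with TNF (80.0% lower). Mimic against control differences leaned on the UTR, with rho of 0.17 and 0.15 with UTR length and 0.20 and 0.17 with A+T content across genes, which are not independent replicates. Against 417 other 7mers of the same base composition, the 7mer-m8 genes lay low: their differences were 0.03 and 0.01, against medians of 0.09 and 0.07, and 2 of the 417 lay lower in each pair. With the antagomir the site genes lay below those without, by -0.02 unstimulated and -0.20 with TNF, and 351 and 110 of the 417 other 7mers lay below the 7mer-m8. In the TNF pair of the antagomir arm rho with UTR length was -0.35. The direction of the first 3 of these 4 differences turned when the background was matched on UTR length, to -0.03, -0.03 and 0.03, and the fourth shrank to -0.045. With the trend with UTR length and base composition removed the fourth was -0.0034. With 8mer sites alone both mimic differences turned, to -0.034 unstimulated and -0.053 with TNF.

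**Figure D4:**
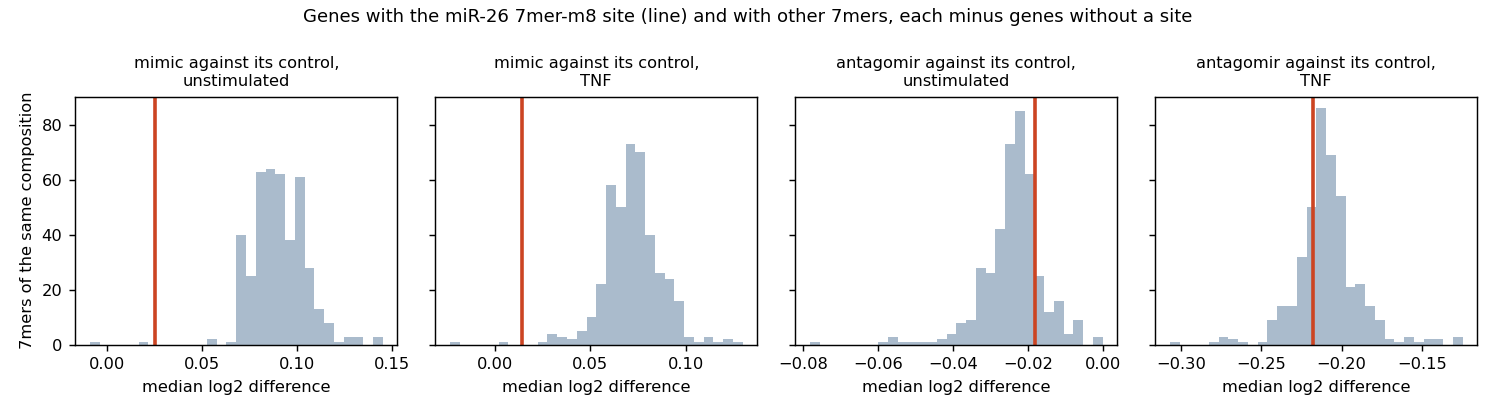
Median log2 difference of genes holding each of 417 7mers of the same base composition as the miR-26 7mer-m8 site, minus that of genes without a miR-26 site (x axis), as the number of 7mers (y axis) in 4 pairs of libraries, with the line at the site itself. In each mimic pair 2 of the 7mers lay below the site, and in the antagomir pairs 351 and 110 did.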

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

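The tests that weigh an explanation, the comparisons between the arms and the ranking of 7mers with the UTR trend removed were tests chosen only after the result was seen.

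Interferon-stimulated genes responded more to TNF in the antagomir arm than in the mimic arm, with a median difference of 1.39 and 35 of 35 genes higher (camera adjusted p = 9.065e-27 for the interaction of arm and stimulation; adjusted p = 0.245 with an estimated correlation). In this fit 23 members passed adjusted over the list alone and none over all genes tested, with 558 genes at an unadjusted p under 0.05 in limma against 505 by chance. ISG15, a ubiquitin-like antiviral protein, went from 5.59 to 6.35 in the mimic control and from 5.73 to 8.32 in the inhibitor control. MX1, an antiviral GTPase, went from 0 to 3.98 and from 0 to 6.52, and IFIT1, which binds foreign RNA, from 2.53 to 3.35 and from 2.96 to 5.88. These genes were chosen after their values were seen. Over the 17 members above 0 in all 8 libraries the median difference was 0.91 (camera adjusted p = 9.268e-20), and no biological explanation was tested.

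By the same interaction, the TNF response of other lists differed between the arms, in each case with adjusted p of 0.631 or more with an estimated correlation. The median difference, antagomir arm minus mimic arm, was 0.23 for cytokines and chemokines (camera adjusted p = 0.0114), 0.34 for NF-kB feedback and response genes (0.0009793), 0.27 for MHC class I antigen presentation (0.0114) and -0.29 for immediate early and AP-1 genes (0.001873). It was -0.16 for G1/S and DNA replication genes (0.016) and 0.15 for ribosomal protein genes (0.016). The median response of ribosomal protein genes was -0.08 with the mimic control, 0.02 with the mimic, -0.10 with the inhibitor control and 0.31 with the antagomir. The ribosomal difference thus rested on the antagomir pair, whose TNF library had rho of -0.32 with UTR length. ATP5J2, a subunit of ATP synthase, was the 1 gene called, at -7.22, being listed at 0 in both unstimulated libraries of the mimic arm and between 7.13 and 7.62 in the other 6. The mimic effect differed from the antagomir effect at 13 genes.

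A library stood apart from the other 3 of its stimulation in 5 of 64 groups of 4 by Dixon's test, which flags about 1 group in 20 by chance, or 3.2 here. The antagomir library with TNF had the highest sum of linear levels, 365015, and the lowest median over tested genes, 3.41. The unstimulated mimic library had the highest rho between A+T content of the UTR and deviation from the mean, 0.199, and a median of 1.57 over NF-kB feedback and response genes. The mimic library with TNF had a median of 5.28 over MHC class I genes.

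Chance is argued against as the source of the TNF result, though 35 splits are too few to exclude it. The fit used for this had no transfection term, unlike the one that called 1258 genes. The real split of the 8 libraries called 800 genes, and 1 of 35 splits called as many. Of the other splits, the highest called 22. That split was mimic arm against antagomir arm, a structure of the samples. With a stimulation term the split by arm called 93 genes and the highest of the others called 5. Of the 34 splits, 1 called as many. Many of the 34 separate libraries of the same transfection, so they are not a reference for a difference between arms. Among splits that keep each transfection whole, the mimic control with the mimic, which is the split by arm, called 93. The mimic control with the inhibitor control called 0, and with the antagomir 5. Such splits are too few to weigh chance for the arms, and no conclusion is drawn.

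Genes induced by TNF responded less with the mimic than with its control, with a median of -0.13. Levels listed at 0 do not account for it, since the 168 induced genes above 0 in all 8 libraries gave -0.11. That lay below all of 10000 random lists drawn from other genes. Levels just above 0 stayed in this set, so their part was not tested. Selection of genes on a high mimic control response does not either. This rests on 387 genes chosen in the antagomir arm alone by a looser rule, a 2-fold rise at an unadjusted limma p under 0.05. They gave -0.095, again below all random lists. A response smaller as a whole, in both directions, could produce the pattern: the 114 genes that fell at least 2-fold had a median of 0.17, above 99.95% of random lists. The 40 NF-kB feedback and response genes showed little of it. Their median response was 2.55 with the control and 2.56 with the mimic, and their median difference was -0.03 (6.69% of random lists lower). The 21 cytokines and chemokines had -0.22 (0.69% lower). Whether the mimic or an unequal stimulation of 1 library is the source stays open, with 1 library per condition.

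Genes with a miR-26 site lay lower with the mimic after the trend with UTR length and base composition was removed from each difference. Chance among 7mers and a remainder of the trend are argued against, since the 7mer-m8 had rank 1 of 15316 7mers by its joint score over the 2 mimic pairs, and 0 of 417 7mers of the same composition scored lower. Repression of site genes by the mimic through the seed may be the source. Genes with an 8mer lay at -0.12 relative to those with only a 7mer. The standard error of 0.03 is taken across genes, which are not independent replicates, and holds no spread between transfections. Of genes with an 8mer, 7.86% lay lower by over 0.5 in both pairs against 2.35% of genes with no 6mer. This is a hypothesis found and tested on the same data, and the planned difference without the trend removed went the other way. In the pairs taken singly the 7mer-m8 ranked 2 unstimulated and 1 with TNF. In data simulated from the unstimulated pair alone, a 7mer with a shift of 0.1 ranked first in 15 of 20 draws, and that shift is larger than the means of -0.070 and -0.077 seen for the 7mer-m8 genes.

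MALT1 lay lower with the mimic and also with the antagomir, at -1.74 unstimulated and -1.83 with TNF against the inhibitor control. Mimic RNA in the antagomir libraries is argued against by the rank of the miR-26 7mer-m8 in the antagomir pairs, 7961 of 15316. Loss of transcripts with long 3-prime UTRs is argued against by MALT1 staying at -1.58 or lower in both pairs with the trend removed. Spread of genes at such low levels is not excluded: 18 of 2023 genes of similar mean level lay as far down in both pairs, MALT1 among them (0.890%, 95% interval 0.528% to 1.40%, taking genes as independent, which they are not). Of the 18, 11 were listed at 0 in both antagomir libraries, which MALT1 was not. The cut set for excluding it was 1%, which lies within that interval. An effect of the antagomir itself and a difference between the cultures could each remain as the source, and neither was tested. The MALT1 level rests on 1 RefSeq transcript in the file, the other being listed at 0. Before the pseudocount that transcript was at 0.05 and 0.41 with the antagomir, near the smallest values above 0. It was at 0.95 and 1.11 with the mimic. The pseudocount makes differences at such levels smaller.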

How the results depend on the processing

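The alternatives for genes above 0 in all 8 libraries, for levels under 1 set to 1 and for the removed UTR trend, the left-out libraries for the lists and for the difference of effects, and limma without the trend for that difference, were tests chosen only after the result was seen. Leaving out 1 library leaves its condition unsampled and 2 residual degrees of freedom, and an arm alone leaves fewer still. The causes of the other shifts below were not tested.

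The 1258 genes for TNF became 0 in the mimic arm alone and 0 in the antagomir arm alone (1932 and 1779 at an unadjusted p under 0.05 in limma), 800 with no transfection term (734 shared) and 95 to 306 with 1 library left out, lowest without the inhibitor control with TNF. They were 1041 to 1476 under the other alternatives. The 16 genes for the mimic became 10 with a pseudocount of 0.1, 29 with no trend in limma, 0 in the mimic arm alone (1590), 0 refitted on genes above 0 in all 8 libraries (1404) and 2 to 10 with 1 library left out. The 11 for the antagomir became 17 with no trend in limma, 0 in its arm alone (387), 1 refitted on genes above 0 and 0 to 27 with 1 library left out. None was called by limma without any 1 library of the mimic arm (477 to 511 at an unadjusted p under 0.05) and 27 were called without the unstimulated antagomir library. The 13 for the difference of effects became 20 with quantile normalization, 21 with no filter, 28 with no trend in limma and 0 refitted on genes above 0 (1486). They became 22 with levels under 1 set to 1, 8 with the UTR trend removed and 0 to 26 with 1 library left out.

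Of the lists, 8 for TNF, 3 for the mimic and 7 for the antagomir, 0, 0 and 0 were called by camera with an estimated correlation. With the UTR trend removed 4 were called for the antagomir, and 6 to 9, 3 to 5 and 3 to 7 with 1 library left out. The TNF response with the mimic, -0.13, became -0.17 with genes induced at least 4-fold, -0.11 with genes above 0 and -0.20 with the UTR trend removed, and was -0.14 to -0.13 under the other 3. With the antagomir, 0.0011 became -0.080 with quantile normalization, -0.0035 with genes induced at least 4-fold and -0.011 with the UTR trend removed.

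The seed site difference for the mimic, unstimulated (0.049), reversed to -0.034 with 8mer sites alone, -0.032 with the background matched on UTR length and -0.058 with the UTR trend removed, and was 0.025 with 7mer-m8 or 8mer sites and 0.027 with quantile normalization. With TNF (0.032) it reversed to -0.053, -0.029 and -0.064 in the same order, and was 0.014 with 7mer-m8 or 8mer sites, 0.020 with a mean level of at least 5 and 0.015 with quantile normalization. For the antagomir, unstimulated (-0.016), it reversed to 0.026 with the matched background, 0.0032 with quantile normalization and 0.0053 with the UTR trend removed. With TNF (-0.20) it was -0.22 with 8mer sites alone, -0.218 with 7mer-m8 or 8mer sites and -0.045 with the matched background. It was -0.218 with a mean level of at least 5, -0.224 with a pseudocount of 0.1, -0.139 with quantile normalization, -0.213 with genes above 0 and -0.0034 with the UTR trend removed.

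Of single genes, HMGA1 with the antagomir reversed to -0.29 without the unstimulated inhibitor control (range 0.71 down to -0.29 over left-out libraries). EZH2 with the antagomir reversed to 0.13 without the antagomir library with TNF (range -0.56 to 0.13), and FDPS with the antagomir to -0.0051 with the UTR trend removed. All 64 named genes called for TNF, 16 for the mimic and 11 for the antagomir lost the call under at least 1 alternative. None of them reversed. An arm alone called no gene in any of these comparisons, so each call had to be lost there. The loss of a call under at least 1 alternative therefore does not measure how firm it is. Over the alternatives run, the TNF call was kept for CXCL8 in 15 of 17 and for KRT17 in 5 of 18. Depth is unknown, so what it limits could not be computed.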

Other observations

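The comparison of the arms was a test chosen only after the result was seen, and the genes named for it were chosen after their values were seen.

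Immediate early genes were higher in the antagomir arm than in the mimic arm, with 6 of 18 measured members called and a median of 1.06 (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.989e-08; adjusted p = 0.492 with an estimated correlation). EGR1, a growth factor-induced transcription factor, was higher by 4.23 ± 0.07, DUSP1, a phosphatase of stress kinases, by 1.98 ± 0.21, IER2 by 1.78 ± 0.16 and MYC by 0.89 ± 0.09. FOS, a subunit of AP-1, was listed at 0 in all 4 libraries of the mimic arm and was 7.01, 4.68, 6.50 and 4.46 in the antagomir arm. Between the 2 control transfections alone, EGR1 differed by 4.58 ± 0.10 (limma adjusted p = 0.001093). These standard errors rest on how much the TNF response varied, not on the spread between the transfections of an arm. Unstimulated EGR1 was 8.56 with the inhibitor control and 7.19 with the antagomir.

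Other genes higher in the antagomir arm were SFRP2, a Wnt antagonist, by 2.27 ± 0.06 and HES1, a Notch target, by 2.21 ± 0.10. So were the gelatinase MMP2 by 1.58 ± 0.13, KLF2 by 1.55 ± 0.11, CTGF, a matricellular protein, by 1.54 ± 0.18 and NQO1, an NRF2 target, by 1.12 ± 0.06. Lower were CHMP3, of membrane scission, at -2.17 ± 0.09, NPPB at -1.97 ± 0.07, the histone deacetylase HDAC2 at -1.56 ± 0.19, CNN1 at -1.51 ± 0.08 and IGFBP3, which binds insulin-like growth factors, at -1.22 ± 0.10. In all limma called 174 genes, 100 higher and 74 lower, and 282 in a refit on the genes above 0 in all 8 libraries alone. These counts also leave out the spread between the transfections of an arm. The 174 genes that differed between the arms became 2 without the unstimulated mimic library and 279 without the unstimulated antagomir library. The arms differ in the kind of small RNA, and a difference of day or culture between them is not given in the labels.

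Of the genes in the file, 261 were listed at 0 in some libraries and had a linear level of 8 or more in all others, 89 of them at 0 in 1 library alone. RPLP1, a ribosomal protein, was listed at 0 in the unstimulated antagomir library and between 7.67 and 9.68 on the log2 scale in the other 7, and was chosen after its values were seen.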
